A study of Arabidopsis thaliana with 96 samples.

How the data were processed

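Seedlings of Arabidopsis thaliana were grown in the dark (etiolated) for 3 days after 2 h of light to induce germination, per the labels' protocols, and were treated with jasmonate (JA). The series holds 96 samples. RNA was sequenced from 59 libraries, binding of tagged transcription factors in seedlings was measured by chromatin immunoprecipitation (ChIP-seq) in 15 samples with a peak list, and binding of 9 factors made in vitro to naked genomic DNA was measured by DAP-seq with 1 list per factor. The ChIP-seq samples of histone marks and the IgG controls, 13 samples, were not analysed here. ChIP-seq used an antibody against GFP on lines that carry a factor with a YPet tag, after 2 h of air or JA, per the labels.

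For the time course, the authors deposited expected counts and TPM per transcript; expected counts were summed per gene and rounded here, and TPM were not used. For the first and the second experiment the authors deposited whole counts per gene. The submitters' processing notes name Trim Galore 0.4.5, TopHat2 2.1.1, HTSeq, edgeR 3.6.2 and Salmon 0.8.1 for the RNA libraries, without saying which made which file; the build is TAIR10. The authors also deposited a table per time of the time course with a log2 fold change, a log2 mean CPM, a likelihood ratio score, and a p-value with its adjusted value, per the file headers. Peak lists hold a score per summit, and the deposited files do not say how it was scaled. The notes name Bowtie2 2.0.5 and MACS2 2.0.10 for ChIP-seq, and Bowtie2 with SICER for DAP-seq, whose deposited events are 200 bp wide with a score of at least 5. MYC2 replicate 1 carries the RNA tools in its notes, and its list holds broad intervals (median width 9049 bp, the widest 54195 bp, 1766 lines that name 1283 distinct intervals) where all other ChIP-seq lists hold single summits.

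Genes carry locus identifiers in the files. Symbols came from a table of the TAIR10.1 assembly, which matched 33437 of 34212 genes of the time course and 32835 of 33602 genes of the other experiments; 10617 and 10654 of them had a symbol. In the first experiment the names of the untreated files mention air while the labels give 0 h of JA; the labels were followed. The labels do not say whether libraries of a group came from separate cultures, so p-values measure the spread between the libraries. Total counts ranged from 29.28 to 43.88 M in the time course (median 38.37), from 3.15 to 18.81 M in the first experiment (median 14.65) and from 2.48 to 52.9 M in the second (median 8.62). In the second experiment, reads that matched more than 1 place made up 17.4 to 68.7% of all reads. The highest share was in Col-0 0.5 h replicate 1, which was also the shallowest library.

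Each experiment was fitted on its own in edgeR 4.0.16 with limma 3.58.1 under R 4.3.3. Genes were kept by filterByExpr with the groups (22330 genes in the time course, 20492 in the first and 19898 in the second experiment), libraries were scaled by TMM, 1 mean was fitted per group, and contrasts were tested with the quasi-likelihood F test and Benjamini-Hochberg adjustment over the genes kept. A gene is called at an adjusted p under 0.05. The biological coefficient of variation was 25.1% in the time course, 20.1% in the first and 10.8% in the second experiment. Standard errors of log2 fold changes were taken from the fold change and its F statistic. The labels give replicate numbers without saying that libraries of 1 number belong together. After the group means were removed, all 3 pairs of libraries with the same number correlated above 0.1 at 0.5, 1, 2, 4, 12 and 24 h of the time course against 0 h, and not at 0.25 or 8 h or in any 2-group comparison of the other experiments. At these 6 times the fit with the number as a replicate block is given where it changes a call or a count. That the pairs are read per comparison was settled after the blocked counts had been seen. The difference of the JA response between genotypes was tested as the interaction contrast. Values given as counts scaled to library size (CPM) were computed with the TMM library sizes. Calls depend on depth and spread. On simulated counts made from the real means and library sizes with 200 changed genes, edgeR recovered 66% of 2-fold and 84% of 4-fold changes at 4 h of the time course. For Col-0 at 4 h the shares were 40 and 78% in the first experiment and 80 and 96% in the second. False calls made up 6.77, 8.77 and 7.43% of calls.

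Before the data were examined, 22 gene lists of 305 members were written from textbook knowledge; 4 members were left out because the reference pairs the identifier with another name. The lists cover JAZ repressors, jasmonate biosynthesis, jasmonate catabolism, MYC family and co-regulators, MYC branch defence, ERF branch defence, aliphatic glucosinolates, indole glucosinolates and tryptophan, sulfur assimilation, anthocyanin and flavonoid genes, ethylene signalling, auxin and growth, cell cycle, circadian clock, salicylic acid response, abscisic acid response, rapid touch and stress response, heat shock, light response and photosynthesis, seed storage and embryo, root cell markers, and xylem and secondary wall. The last 5 lists with the clock and touch lists were meant to show light, heat, handling, time of day, germination stage and organ makeup. Lists were tested with camera from limma at a preset correlation of 0.01, adjusted over the 22 lists of a contrast, and again with an estimated correlation. Genes to name were fixed by a rule: the 4 ChIP-seq factors, the DAP-seq factors in the time course, and in 5 main comparisons (2 h and 24 h of the time course, Col-0 at 4 h, the genotypes at 0 h and the 4 h interaction of the second experiment) the 5 highest and 5 lowest called genes with a mean of at least 5 CPM and no overlap between groups (no such condition for the interaction), and up to 3 called members of each list with at least 3 called members. Reads shared by near-identical copies can be split in either direction by the counting, so the LHCB1, LHCB2, AOC and small HSP genes are uncertain one by one. The counting's use of strand is not stated, so overlapping and antisense genes are uncertain too.

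Windows of 150 bp around each summit, or the deposited interval, were merged into regions when they shared at least 1 bp, and a region was kept when at least 2 replicates had a window in it. Organelle summits were left out. Expected numbers came from 100 random placements on the same chromosomes. The design included the intervals of MYC2 replicate 1, which raise the chance overlap, so the number of MYC2 regions, their overlap with MYC3 and the tests of bound genes are also given from the summit lists alone. That second set was chosen after the lists had been seen, except for the number of regions, where leaving out each replicate was planned. A region was assigned to the nearest protein-coding gene span (0 bp inside it) when within 1000 bp of the region's centre. Broad intervals of MYC2 replicate 1 can join several summits into 1 region, which is then assigned by its centre alone. Of the MYC2 regions, 32.4% lay inside genes, against 23.5% from the summit lists alone. The plan named transcription start sites, but the table gives spans without strand. As a check that the spans and the peak lists share coordinates, 23.5% of MYC2 summit regions lay inside genes, against 62.5 and 61.7% when shifted by 5000 bp either way. Sequence motifs were not analysed here. Overlaps with called genes used Fisher's exact test in R. The permutation test of the STZ lists used scipy 1.17.1 (Python 3.11.15, numpy 2.4.6, pandas 2.3.3), and plots used matplotlib 3.10.9. On simulated peak lists of single summits at widely spaced sites, all 500 of 500 shared sites were found. These lists held no close summits or broad intervals, so the merging of those was not checked.

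Alternatives were a test by DESeq2 1.42.0, relative log expression size factors, no filter on low counts, the replicate number as a block, a fold of at least 2, a fit of only the groups compared, and leaving out each replicate in turn. For binding they were a logistic regression with expression and gene length, other windows, distances, score limits and numbers of replicates, and for lists the estimated correlation.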

Results

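Transcripts and transcription factor binding were measured in dark-grown seedlings of Arabidopsis thaliana treated with jasmonate (JA), a lipid-derived hormone of wounding and defence. Col-0 is the wild type, and myc2 carries a mutation in MYC2, the basic helix-loop-helix factor that activates many JA genes and is held back by JAZ repressors until JA is sensed. The RNA libraries belong to 3 experiments. A time course of Col-0 had 3 libraries at each of 0, 0.25, 0.5, 1, 2, 4, 8, 12 and 24 h of JA (27 libraries, 29.28 to 43.88 M counts each). The first experiment had 2 libraries of each genotype at 0 and 4 h (8 libraries, 3.15 to 18.81 M). The second had 3 libraries of each genotype at 0, 0.5, 1 and 4 h (24 libraries, 2.48 to 52.9 M). By the labels the only untreated libraries are those of 0 h, so each later time differs from them by JA and by elapsed time together. In the first experiment the names of the untreated files mention air, and whether those seedlings were kept in air for a time is not stated. ChIP-seq peak lists covered MYC2 (4 replicates), MYC3 (3), ANAC055 (3) and STZ (3 in air and 2 in JA), and DAP-seq lists covered 9 further factors.

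The time course asked which transcripts follow JA and when. At 0.25 h HY5, a basic leucine zipper factor of light signalling, rose by 1.18 ± 0.20 on the log2 scale (SE, n = 3 libraries per time), and it rose by 2.27 ± 0.21 at 0.5 h and 2.70 ± 0.21 at 1 h. The call of HY5 at 0.25 h was lost without any 1 library of 0 h and without 0.25 h replicate 2 or 3. A fit of only the groups compared kept none of the calls at 0.25 h, those of HY5 and the touch list included. Rapid touch and stress genes were higher as a list at 0.25 h: 3 of 19 members rose among all genes tested and 16 adjusted over the list alone (camera adjusted p = 6e-26). STZ, a zinc finger repressor of stress responses on that list, stood at 36.1 ± 31.9 CPM (SD, n = 3) at 0.25 h against 1.76 ± 0.300 at 0 h, a difference that did not pass edgeR's test (adjusted p = 0.0785) but passed with DESeq2 and without 0.25 h replicate 1. That library held 4.03 CPM of STZ against 36.5 and 67.8 in the other 2. The circadian clock list rose at 0.5 h (3 of 17 members, 8 adjusted over the list alone) and at 1 h (9 of 17, 14 adjusted over the list alone; camera adjusted p = 3.3e-42). The calls of the touch list at 0.25 h and of the clock list at 0.5 and 1 h held with an estimated correlation. JAZ repressors were higher as a list at 0.5 h with no member called among all genes and 8 of 13 adjusted over the list alone. That call was lost at an adjusted p = 0.16 with an estimated correlation. Xylem and secondary wall genes were lower as a list at 0.25 h (median −0.30, 0 of 8 members called by edgeR among all genes or over the list alone), lost at an adjusted p = 0.47 with an estimated correlation.

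Over the whole time course, edgeR called 13 genes higher and 5 lower at 0.25 h, 56 and 18 at 0.5 h, 261 and 47 at 1 h, 740 and 167 at 2 h, 36 and 8 at 4 h, 43 and 11 at 8 h, 224 and 202 at 12 h, and 1933 and 2081 at 24 h. These counts depend on the fit. With the replicate number as a block they were 160 higher and 41 lower at 0.5 h, 651 and 146 at 1 h, 1844 and 910 at 2 h, 440 and 150 at 4 h, 896 and 764 at 12 h, and 3611 and 3280 at 24 h, the 6 times at which libraries of the same number varied together. At 24 h more genes were then higher than lower, as at a fold of 2 or more without the block (883 and 612) and in the authors' deposited table (2951 and 2674). A fit of only the groups compared called 10 genes at 0.5 h, 140 at 1 h, 20 at 4 h, 1 at 8 h and 1297 at 24 h. The genes at an unadjusted p under 0.05 without the block numbered 3965 at 2 h and 2212 at 4 h. The block made camera pass for JA catabolism at 0.5 and 4 h, the MYC family at 4 h and anthocyanin genes at 24 h. With it the clock list no longer passed at 4, 12 and 24 h, nor seed storage genes at 12 h. The authors' deposited tables, from a likelihood ratio test, hold 2524 genes with an FDR under 0.05 at 2 h, 986 at 4 h and 5625 at 24 h, and 841 of the 878 genes called here at 2 h and present in the authors' deposited table have the same direction and an FDR under 0.05 there. Across 19800 genes, which are not independent replicates, the log2 fold changes here and in the authors' deposited tables correlated with Pearson's r of 0.935 (4 h) to 0.977 (24 h). DESeq2 called more genes than edgeR at each time, with 1507 at 2 h and 275 at 4 h. Leaving out single libraries moved the count at 2 h to 331 (0 h replicate 2), 385 (0 h replicate 3), 461 (2 h replicate 2) or 550 (2 h replicate 3), and the count at 4 h was 7 without 0 h replicate 2 or 3, 11 without 0 h replicate 1, 13 without 4 h replicate 1 and 14 without 4 h replicate 3. At 0.25 h it was 3 without 0 h replicate 1 or 3 or 0.25 h replicate 3, 4 without 0 h replicate 2 and 130 without 0.25 h replicate 1. At 0.5 h it was 39 to 49 without any library of 0 h or without 0.5 h replicate 3, and 256 without 0.5 h replicate 1. At 1 h it was 195 and 159 without 0 h replicates 2 and 3, and 506 and 175 without 1 h replicates 1 and 3. At 8 h it was 8, 2 and 1 without 0 h replicates 1, 2 and 3, and 14, 13 and 91 without 8 h replicates 1, 2 and 3. At 12 h it was 157, 110 and 117 without 0 h replicates 1, 2 and 3, and 192 and 117 without 12 h replicates 2 and 3.

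**Figure D1:**
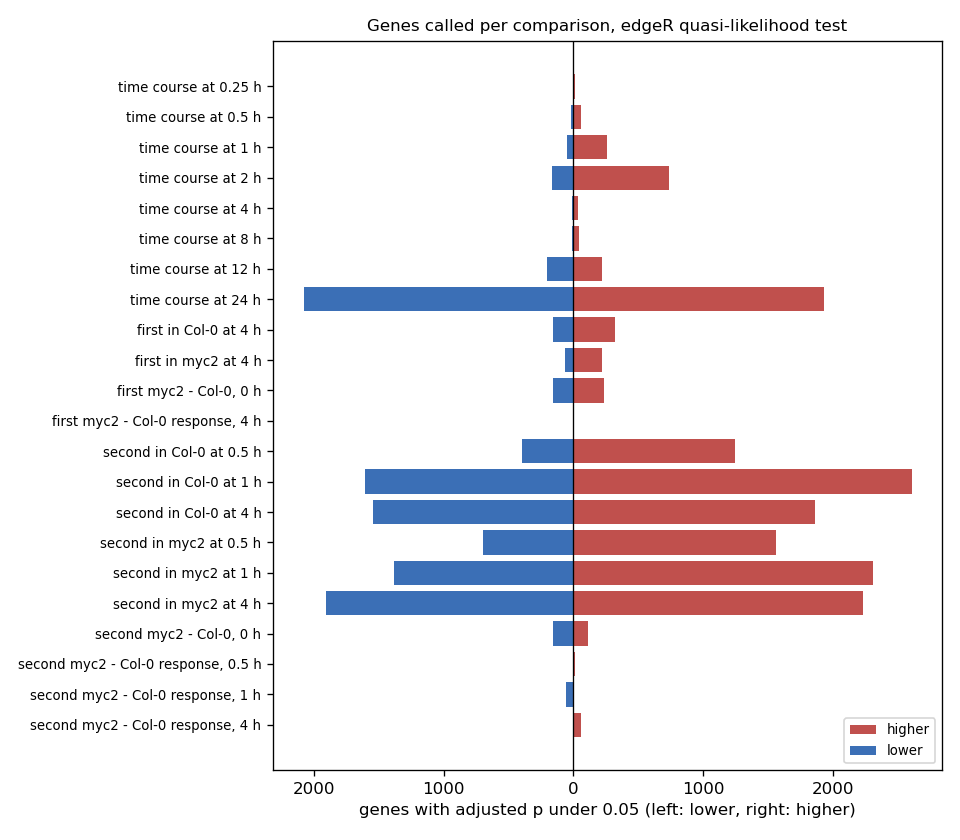
Number of genes called higher (bars to the right) and lower (bars to the left) by edgeR's quasi-likelihood test in each comparison, with the comparison on the vertical axis and genes on the horizontal axis. The time course has its highest counts at 24 h (1933 higher, 2081 lower), and the tests of the genotype difference in JA response call from 1 to 66 genes.

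At 2 h of JA, genes of light harvesting and LOX2 of JA synthesis were among those with the largest increases. LHCB2.2 and LHCB1.1, chlorophyll-binding proteins of photosystem II, reached 529.9 ± 95.3 and 429 ± 53.1 CPM (SD, n = 3) from 8.14 ± 2.82 and 4.18 ± 3.47 at 0 h, and LHB1B1 of the same family reached 140.3 ± 44.7 from 1.12 ± 0.701. LOX2, the chloroplast lipoxygenase of JA synthesis, was at 7.51 ± 6.58 against 0.0694 ± 0.0184 CPM, and AT1G53875 at 6.46 ± 4.15 against 0.0183 ± 0.0316. Of the light response and photosynthesis list, 13 of 20 members rose among all genes and 17 adjusted over the list alone (camera adjusted p = 5.9e-28), among them LHCB2.1 (log2 change 5.47 ± 0.72, SE) and ELIP1, an early light-induced protein (4.44 ± 1.18). Heat shock genes rose in 9 of 13 (12 adjusted over the list alone), with HSP17.6II at 3.88 ± 0.90, and clock genes rose in 8 of 17 with RVE2 lower by −1.13 ± 0.25 (9 higher and 2 lower adjusted over the list alone). PRR9 and PRR7, which repress the morning clock genes, rose by 3.90 ± 0.49 and 2.42 ± 0.46. These 3 lists passed camera with an estimated correlation too. Indole glucosinolate and tryptophan genes, which make sulfur-containing defence compounds, rose in 8 of 15 (9 adjusted over the list alone), including CYP79B2 (139 ± 8.29 against 48.9 ± 13.3 CPM), UGT74B1 (1.38 ± 0.30) and ASA1 (1.61 ± 0.36). Their camera adjusted p of 1.8e-07 became an adjusted p = 0.12 with an estimated correlation.

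JA synthesis genes rose at 2 h in 4 of 14 (8 adjusted over the list alone), with AOC2 at 3.14 ± 0.85 and AOS at 2.28 ± 0.58 (adjusted p = 0.15 with an estimated correlation). JAZ repressors rose in 1 of 13 (8 adjusted over the list alone; adjusted p = 0.45 with an estimated correlation), and anthocyanin genes in 3 of 15 (6 adjusted over the list alone; adjusted p = 0.37 with an estimated correlation), with F3H, a flavanone hydroxylase, at 3.55 ± 0.76. MYC2 itself was at 150.0 ± 35.3 against 90.4 ± 10.8 CPM, which did not pass (log2 change 0.73 ± 0.30), nor did MYC3, STZ or ANAC055. With the replicate block MYC2 passed at 1, 2 and 4 h, STZ at 0.5 and 24 h, ANAC055 at 12 h and MYC3 at 24 h. Genes that fell included AT1G72290 (−2.49 ± 0.65), the cyclin CYCP4;2 (−1.83 ± 0.44), AT5G02540 (−1.79 ± 0.35), the CBL-interacting kinase CIPK16 (−1.76 ± 0.38) and AT5G39240 (−1.76 ± 0.24). The calls of LHB1B1, LHCB1.1, LHCB2.1, LHCB2.2, PRR9, PRR7, LNK1, UGT74B1, HY5, AT5G02540 and AT5G39240 held without each library compared, and those of LOX2, AOC2, AOS, ELIP1, F3H, CYP79B2, ASA1 and the HSP17.6 genes did not.

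At 24 h the JA marker genes were far above 0 h. LOX2 reached 454 ± 354 CPM (SD, n = 3) from 0.0694 ± 0.0184, BGLU18, a beta-glucosidase, 177 ± 135 from 1.04 ± 0.423, and the storage protein VSP2 112 ± 75.6 from 5.43 ± 2.61. JAZ repressors rose in 9 of 13 (11 adjusted over the list alone), led by JAZ5 (5.69 ± 1.27), JAZ9 (4.29 ± 0.88) and JAZ10 (3.96 ± 0.97), JA synthesis genes in 8 of 14 (10 over the list alone), MYC branch defence genes in 6 of 8 (7 over the list alone). Indole glucosinolate genes rose in 10 of 15 (11 over the list alone), with CYP81F2 at 4.71 ± 0.80. Genes of JA catabolism rose in 4 of 9 (6 higher and 1 lower over the list alone), ERF branch defence genes in 2 of 8 (3 over the list alone), and salicylic acid response genes in 3 of 13 (4 over the list alone), among them the glutaredoxin GRX480 (3.78 ± 0.62). MYC2 rose by 1.44 ± 0.30 to 245 ± 36.3 CPM, ANAC055 by 2.76 ± 0.60, WRKY51 by 1.57 ± 0.37 and ATAF2 by 1.12 ± 0.29. None of the list calls at 24 h held with an estimated correlation. The nearest were MYC branch defence at an adjusted p = 0.051 with an estimated correlation and JA synthesis at an adjusted p = 0.092.

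Root cell markers fell at 24 h in 6 of 9 members (1 higher and 6 lower adjusted over the list alone; adjusted p = 0.18 with an estimated correlation). PRP3, a proline-rich wall protein of root hairs, fell by 2.93 on the log2 scale and LRX1, a leucine-rich repeat extensin, by −2.36 ± 0.50. Other genes that fell were UMAMIT35 (−4.84 ± 0.80), AT3G49960 (−3.54 ± 0.76), FLA6 (−3.53 ± 0.65), XTH12 (−3.49 ± 0.73) and the extensin EXT13 (−3.33 ± 0.55). SULTR1;1, a root sulfate transporter, fell by 3.08 while APK2 of sulfur assimilation rose by 1.46 ± 0.36. GA20OX1 and GA3OX1, enzymes of gibberellin synthesis, fell too (GA3OX1 at −1.28 ± 0.36). Light response genes were higher in 10 of 20 at the same time (13 adjusted over the list alone; adjusted p = 0.20 with an estimated correlation). The count at 24 h fell to 2076 without 24 h replicate 3, to 2439 without 0 h replicate 3 and to 2487 without 0 h replicate 1, and the calls of IGMT1, TAT3, CYP94B1, ERF6, WRKY33, WRKY53, WRKY51, ATAF2, SARD1, GA20OX1 and GA3OX1 were lost without at least 1 library.

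In the second experiment MYC2 transcript checked the genotype labels. At 0 h it was at 46.9 ± 3.77 CPM in myc2 against 163 ± 7.80 in Col-0 (SD, n = 3), with the myc2 libraries at 42.6 to 49.6 and the Col-0 libraries at 155.8 to 171.4. In the first experiment it was at 69.7 ± 4.47 against 143 ± 5.73 (n = 2). Before treatment 112 genes were higher and 160 lower in myc2 (edgeR, 19898 genes). SAG29, a senescence-associated sugar transporter, was higher by 3.09 ± 0.52, bHLH39, a regulator of iron uptake, by 2.19 ± 0.31, AT5G46960 by 1.62 ± 0.29 and AT3G07720 by 1.59 ± 0.11. ECS1 was lower (−3.30 ± 0.42), as were the seed storage-like AT1G03890 (−3.18 ± 0.63), AT5G03350 (−2.47 ± 0.35), the glutathione transferase GSTF6 (−1.98 ± 0.30) and BGLU24 (−1.89 ± 0.41). Abscisic acid response genes split, with PYL6, PYL5 and PYL4, receptors of the hormone, higher and RD29B (−1.09 ± 0.18), HAI1 (−1.19 ± 0.15) and ABI2 lower (3 higher and 5 lower of 13 adjusted over the list alone; camera down, adjusted p = 0.33 with an estimated correlation). Salicylic acid response genes were lower in 2 of 12 (6 adjusted over the list alone; adjusted p = 0.098 with an estimated correlation), and the light response list in 1 of 20 (4 over the list alone; adjusted p = 0.33 with an estimated correlation). Leaving out any Col-0 0 h library gave 123 (replicate 1), 155 (replicate 2) or 130 genes (replicate 3) in place of 272, and leaving out myc2 replicate 3 gave 113.

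Between 0 h and each later time, both genotypes of the second experiment changed widely. In Col-0, 1247 genes rose and 393 fell at 0.5 h, 2609 and 1607 at 1 h, and 1865 and 1543 at 4 h. Of the Col-0 0.5 h libraries, replicate 1 stood apart. Its 10 most abundant genes held 32.6% of its counts, against 6.77 and 6.44% in replicates 2 and 3. In myc2, 1562 rose and 698 fell at 0.5 h, 2312 and 1385 at 1 h, and 2231 and 1905 at 4 h. MYC2 transcript rose in both: in Col-0 to 432 ± 38.9 CPM at 0.5 h, 703 ± 54.0 at 1 h and 366 ± 49.1 at 4 h, and in myc2 to 210.1 ± 14.8, 179.6 ± 27.9 and 179 ± 27.1. ANAC055, a NAC factor downstream of MYC2, rose in Col-0 by 1.71 ± 0.16 at 1 h and in myc2 by 1.35 ± 0.16 at 0.5 h, 1.05 ± 0.17 at 1 h and 0.94 ± 0.17 at 4 h. MYC3, a close homologue of MYC2, did not pass in any of these contrasts. At 0.5 h the clock list rose in 13 of 17 members in Col-0 and 14 in myc2 (14 over the list alone in Col-0, 15 higher and 1 lower in myc2), and JAZ repressors in 9 and 10 of 12 (10 and 10 over the list alone). All 4 calls held with an estimated correlation. Ethylene signalling genes fell at 1 h in 9 of 12 in Col-0 with 1 higher (the same over the list alone) and in 8 of 12 in myc2 (9 over the list alone), also with an estimated correlation.

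**Figure D2:**
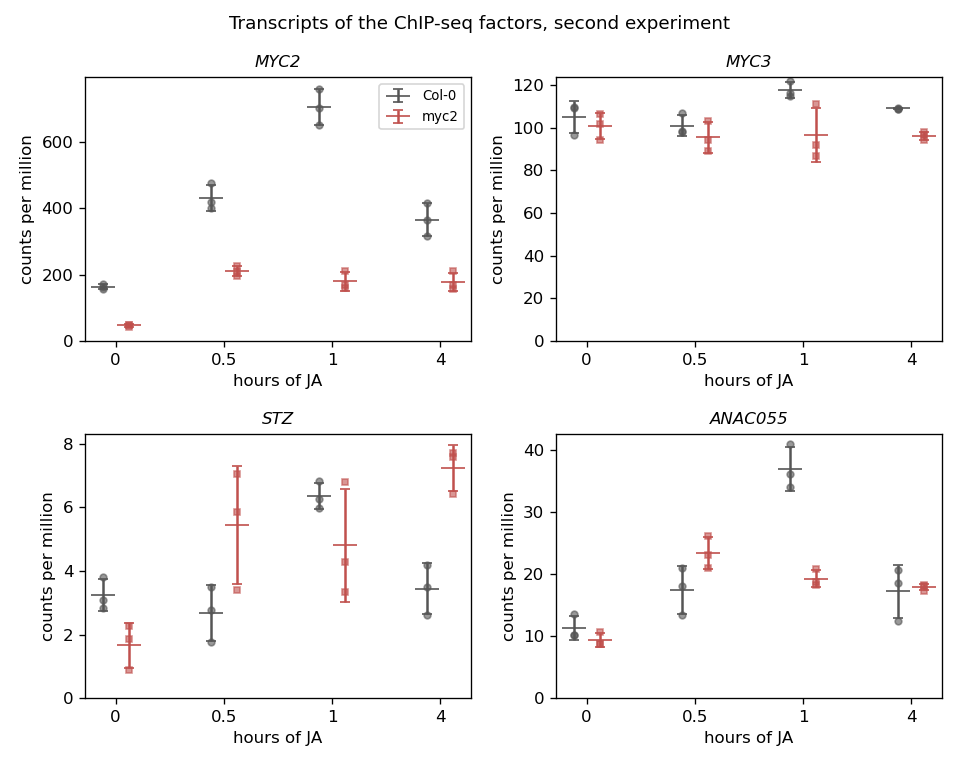
Transcript level in CPM (vertical axis, from 0) of the 4 ChIP-seq factors against hours of JA (horizontal axis, not to scale) in the second experiment. Points are libraries, bars are means and SD (n = 3), grey is Col-0 and red is myc2. MYC2 in myc2 lies below Col-0 at each time and is higher after JA than at 0 h, with a mean of 46.9 at 0 h and 210.1 at 0.5 h.

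At 4 h in Col-0 of the second experiment, LOX2 rose to 423 ± 153 CPM (SD, n = 3) from 0.610 ± 0.956, BGLU18 to 177 ± 61.2 from 0.901 ± 0.367, AT3G28220 to 90.6 ± 30.3 from 0.0797 ± 0.138, LHB1B1 to 59.1 ± 37.1 from 0.430 ± 0.182, and AAE12 to 10.4 ± 5.29 from 0.0773 ± 0.0670. JAZ repressors rose in 10 of 12 (10 adjusted over the list alone; camera adjusted p = 2e-41), with JAZ9 at 4.15 ± 0.17, and JA synthesis genes in 12 of 14 (12 over the list alone; 1.3e-32), with AOS at 3.96 ± 0.19. JA catabolism genes rose in 7 of 8 (7 over the list alone), MYC branch defence in 6 of 9 with VSP2 at 6.45 ± 0.37, ERF branch defence in 4 of 6 with ERF2 at 1.39 ± 0.17, indole glucosinolate genes in 11 of 15 with CYP81F4 at 2.47 ± 0.20, and sulfur assimilation in 7 of 11 with APK2 at 1.99 ± 0.18. The list-alone counts of these 4 were 6, 4, 12 higher and 1 lower, and 7 higher and 1 lower. Heat shock genes rose in 8 of 12 (10 over the list alone) and the clock list had 4 members higher and 10 lower of 17 (11 lower over the list alone), with LHY, a morning clock gene, at −2.01 ± 0.12. All of these calls held with an estimated correlation. MYC2 rose by 1.16 ± 0.12 and ANAC055 by 0.61 ± 0.17, whose call was lost without Col-0 0 h replicate 1 or 3 or 4 h replicate 2.

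Other lists moved less evenly at 4 h. Light response genes were higher in 13 of 20 with 1 lower (13 and 2 over the list alone; adjusted p = 0.060 with an estimated correlation). LHCA1 of photosystem I rose by 3.11 ± 0.20 while HY5 fell by 2.39 to 15.7 ± 0.769 from 82.2 ± 6.28 CPM. Root cell markers fell in 7 of 9 (1 higher and 7 lower over the list alone; adjusted p = 0.083 with an estimated correlation), with RSL4, a root hair growth regulator, at −1.14 ± 0.21. Auxin and growth genes had 10 higher and 3 lower of 21 (11 and 4 over the list alone; adjusted p = 0.20 with an estimated correlation), and anthocyanin genes 7 higher and 2 lower of 15 (7 and 2 over the list alone; adjusted p = 0.11 with an estimated correlation). Abscisic acid response genes had 5 higher and 1 lower of 13, the same over the list alone (adjusted p = 0.20 with an estimated correlation). Cell cycle genes fell in 3 of 16 and did not pass as a list, CYCB1;4 having the largest change (−0.63 ± 0.12). Other genes that fell were CBF3, a cold response factor (−5.29 ± 0.92), the gibberellin oxidase ATGA2OX1 (−4.83 ± 0.75), EARLI1 (−2.83 ± 0.27), HSFA6B (−2.47 ± 0.18) and AT4G17670 (−2.33 ± 0.27). In the time course HY5 at 4 h was at −0.47 ± 0.20 and did not pass, but passed with the replicate block.

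The interaction asked whether the response to JA depends on MYC2. Throughout, a response is larger in myc2 where its log2 change minus that of Col-0 is above 0. It is smaller where this difference is below 0, and genes that fell after JA are counted in the same way. At 4 h in the second experiment the response was larger in myc2 than in Col-0 for 62 genes and smaller for 4 (edgeR, 12 libraries compared). MYC2 itself responded more strongly in myc2 (0.77 ± 0.17), from its lower level at 0 h. Enzymes of indole glucosinolate synthesis stood out: CYP79B2 went from 49.3 ± 9.71 to 844.5 ± 50.2 CPM in myc2 and from 46.1 ± 3.37 to 178 ± 31.7 in Col-0, a difference of 2.16 ± 0.24 on the log2 scale (SE), and CYP83B1 and SUR1 differed by 1.72 ± 0.23 and 1.69 ± 0.19. On this list 7 of 15 members had a larger response in myc2 (10 adjusted over the list alone; camera adjusted p = 1.3e-37). The sulfotransferase SOT17 of aliphatic glucosinolates went from 8.20 ± 1.36 to 65.7 ± 10.6 CPM in myc2 and from 7.19 ± 0.926 to 12.4 ± 2.31 in Col-0 (2.21 ± 0.25). That list had 2 of 8 (4 over the list alone). JA catabolism had 3 of 8 (5 over the list alone), with CYP94C1, which oxidises the active JA-isoleucine, at 2.01 ± 0.40, CYP94B3 at 1.08 ± 0.24 and the amidohydrolase ILL6 at 1.06 ± 0.18. Sulfur assimilation had 2 of 11 (4 over the list alone), and the touch list 1 of 20 (5 over the list alone), STZ, at 2.04 ± 0.43, whose mean at 0 h was 1.67 ± 0.708 CPM in myc2 and 3.24 ± 0.518 in Col-0. These lists held with an estimated correlation, as did ERF branch defence (1 of 6, 3 over the list alone) and ethylene signalling, lower with 0 of 12 called by edgeR and 1 over the list alone. The first experiment, with 2 libraries per group, called 1 gene in its 4 h interaction, and that gene is not among those named here. List results of that interaction are not reported here.

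Of the other genes at 4 h, ECS1 differed by 3.10 ± 0.55, the blue copper protein BCB by 2.21 ± 0.48 and the cytochrome CB5-C by 2.02 ± 0.36. Smaller responses in myc2 were found for GGPS6, a geranylgeranyl diphosphate synthase (−1.86 ± 0.36), AT2G34020 (−0.87 ± 0.16), AT3G57710 (−0.65 ± 0.14) and AT4G36440 (−0.62 ± 0.13). ECS1 was lower in myc2 at 0 h, with 17.38 ± 11.2 CPM in Col-0 and 1.72 ± 0.596 in myc2, and stood at 11.9 ± 4.17 and 10.3 ± 0.604 at 4 h, so its difference lies in the untreated libraries. JAZ repressors had 1 of 12 larger in myc2 (2 over the list alone; adjusted p = 0.14 with an estimated correlation) and JA synthesis 1 of 14 (3 over the list alone; adjusted p = 0.18 with an estimated correlation). The number of genes was 36 without Col-0 4 h replicate 1 and 42 without Col-0 0 h replicate 2, myc2 0 h replicate 1 or myc2 4 h replicate 3, and DESeq2 called 134. The calls of STZ, MYC2, BCB, CYP94B3, CYP94C1, GGPS6, AT3G57710 and AT4G36440 were lost without at least 1 of the 12 libraries, while those of CYP79B2, CYP83B1, SUR1, SOT17, ILL6, ECS1, CB5-C and AT2G34020 held without each.

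**Figure D3:**
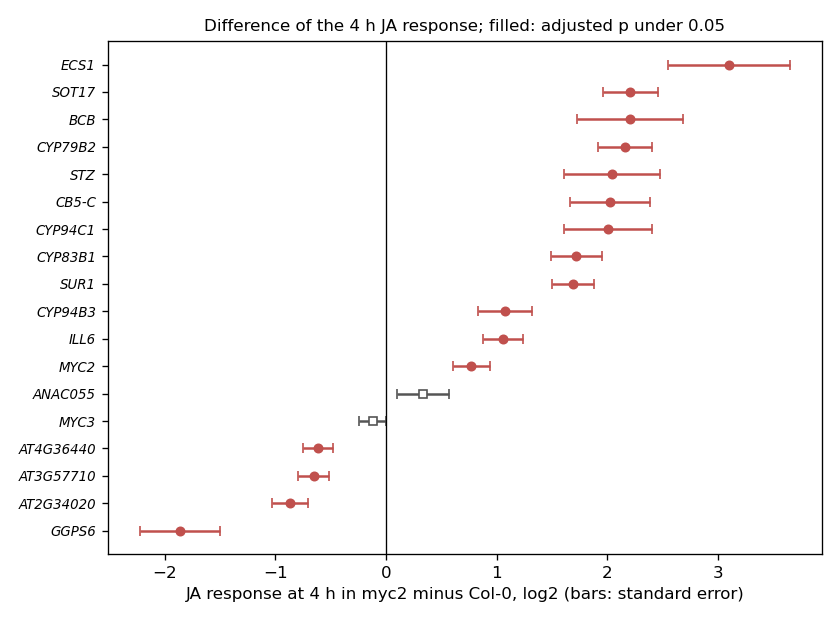
JA response at 4 h in myc2 minus that in Col-0 (horizontal axis, log2; bars are standard errors, n = 3 libraries per group) for the genes named in the second experiment. Filled points passed edgeR's test and open squares did not. CYP79B2 (2.16), SOT17 (2.21) and STZ (2.04) lie to the right of 0 and GGPS6 (−1.86) to the left.

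At 1 h the direction was the other way: 55 genes had a smaller response in myc2 and 2, RPT2 and PKS1, a larger one. JA synthesis genes had 3 of 14 smaller (6 adjusted over the list alone; camera adjusted p = 2.1e-15), AOS at −1.95 ± 0.26, LOX4 at −1.63 ± 0.34 and OPR3, the oxophytodienoate reductase, at −1.53 ± 0.20. JAZ repressors had 1 of 12 (JAZ2, −1.31 ± 0.20; 7 over the list alone), the MYC family 2 of 9 (JAM1, −1.68 ± 0.19, and NINJA, −0.57 ± 0.11; 3 over the list alone) and all 3 lists held with an estimated correlation. The glutathione transferase GSTU6 had the largest difference of all, −2.41 ± 0.20. At 0.5 h, 11 genes had a larger response in myc2 and 1, AT1G23950, a smaller one. The abscisic acid response list had 2 of 13 larger (6 larger and 2 smaller over the list alone; adjusted p = 0.10 with an estimated correlation), HAI1 (1.41 ± 0.20) and RD29B, both of which were lower in myc2 at 0 h. The genes named for 0.5 and 1 h were chosen after their values were seen. The count at 0.5 h moved with many single libraries, to 53 without myc2 0 h replicate 1, 22 without Col-0 0.5 h replicate 1, 19 without Col-0 0 h replicate 1 or 0.5 h replicate 3, 7 without Col-0 0 h replicate 2, 6 without myc2 0.5 h replicate 1, 5 without Col-0 0 h replicate 3 or myc2 0.5 h replicate 2, 4 without myc2 0 h replicate 3 and 2 without Col-0 0.5 h replicate 2.

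The first experiment repeated the 4 h comparison with 2 libraries per group. Its shallowest library, myc2 4 h replicate 1, held 3.15 M counts, and the others held 12.5 to 18.81 M. In Col-0, 325 genes rose and 155 fell, and in myc2 222 rose and 63 fell (edgeR, 20492 genes). JAZ repressors rose in 5 of 12 in Col-0 (11 adjusted over the list alone) and 7 in myc2 (10 over the list alone), JA synthesis genes in 10 of 13 (10 higher and 1 lower over the list alone) and 2 (8 and 1), and heat shock genes in 7 of 12 (9) and 10 (12), all held with an estimated correlation. The light response list was lower in Col-0, with 2 of 20 members lower and none higher (4 lower over the list alone; median −0.06, camera adjusted p = 0.031, adjusted p = 0.56 with an estimated correlation). Seed storage and embryo genes, marks of the germination stage, were lower in myc2 than in Col-0 at 0 h in 10 of 13 (13 over the list alone; camera adjusted p = 6.7e-65, held with an estimated correlation), while 235 genes were higher and 155 lower in all. MYC2 rose by 0.98 ± 0.21 in Col-0, was at 0.64 ± 0.21 in myc2, which did not pass, and was lower in myc2 at 0 h by −1.04 ± 0.21. The interaction called 1 gene, CYP708A3 (−3.10 ± 0.39, named after its value was seen), and DESeq2 called 14. At an unadjusted p under 0.05 in edgeR there were 790 of 20492 genes, a smaller share than the 0.05 that chance alone gives. MYC2 (−0.34 ± 0.29) and STZ (0.70 ± 0.62) did not pass. Leaving out 1 Col-0 library gave 148 (0 h replicate 2), 189 (0 h replicate 1), 155 (4 h replicate 1) or 292 genes (4 h replicate 2) in place of 480. In myc2 it gave 166 and 114 in place of 285 without 0 h replicates 1 and 2. The 390 genes different at 0 h became 72 and 116 without Col-0 replicates 1 and 2, and 93 without myc2 replicate 1. The interaction called 13 genes without Col-0 0 h replicate 1, 2 without Col-0 4 h replicate 2, 4 without myc2 4 h replicate 2, and 0 without either myc2 0 h library or myc2 4 h replicate 1. Without Col-0 4 h replicate 1 it called 1 other gene and not CYP708A3.

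Between experiments the 4 h response of Col-0 was compared gene by gene. Pearson's r of log2 fold changes across genes, which are not independent replicates, was 0.16 between the time course and the first experiment (20232 genes; Spearman's rho 0.09), 0.48 between the time course and the second (19753; 0.39) and 0.45 between the first and the second (19587; 0.32). Of the genes called in both experiments of a pair, 13 of 15, 39 of 39 and 329 of 338 had the same direction. Independent calls would give 0.546 genes higher and 0.0533 lower in both for the first pair, 3.20 and 0.622 for the second, and 30.5 and 12.0 for the third. Without a filter on low counts r was 0.0759 for the time course with the first experiment, 0.17 for the time course with the second and 0.19 for the first with the second.

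**Figure D4:**
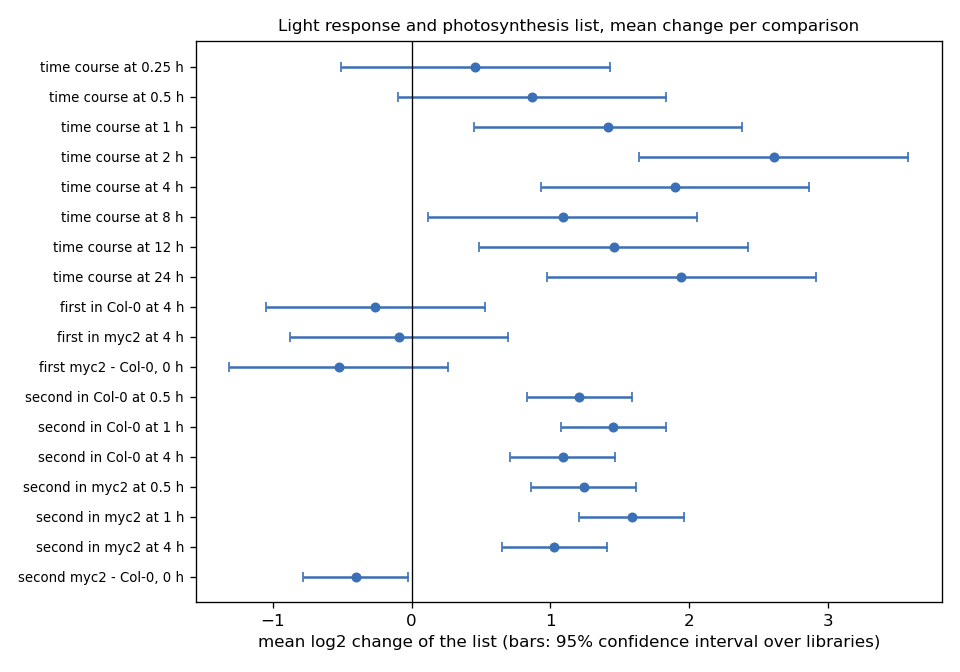
Mean log2 change of the 20 genes of the light response and photosynthesis list (horizontal axis; bars are 95% confidence intervals over libraries) in each comparison (vertical axis). The list is at 2.61 at 2 h of the time course and 1.09 at 4 h in Col-0 of the second experiment, and at −0.26 at 4 h in Col-0 of the first.

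ChIP-seq of MYC2 after 2 h of JA asked where the factor binds. The lists held 1766 lines of intervals (replicate 1) and 953, 7779 and 15296 summits (replicates 2 to 4). On the nuclear chromosomes 5027 regions were found in at least 2 replicates, against a mean of 1472 over 100 random placements (highest 1523), and 647 in all 4. The summit lists alone gave 6731 regions against 337 by chance. The count rests on the deeper lists, since it was 1291 without replicate 3 and 1290 without replicate 4. MYC3 had 3983 regions in at least 2 of 3 replicates (random mean 181), 2646 of them in all 3. Of the MYC3 regions, 94.5% (3766) overlapped a MYC2 region, against 12.1% for random placements on the genome and 14.0% near genes. With the MYC2 summit lists alone it was 91.6% against 2.22%. ANAC055 had 388 regions (random mean 5.10), with 140 left without replicate 1 and 170 without replicate 2.

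MYC2 and MYC3 regions were nearest to each JAZ gene looked up except JAZ4 and JAZ11, and lay at the factors' own genes. On TAIR10 chromosome 1, the MYC2 summit lists gave regions at 26654443 to 26654613 (1 bp from JAZ9, highest score 294) and 26655647 to 26655826 (inside JAZ9), each in all 3 lists, and the MYC3 region with the highest mean rank of score overlapped the first, at 26654435 to 26654617. JAZ10 had a MYC2 region inside the gene on chromosome 5 at 4218678 to 4218894. In the summit lists the MYC2 region with the highest mean rank was 330 bp from MYC2, on chromosome 1 at 11801644 to 11801829. The next were 917 bp from ERF13 (chromosome 2, 18494198 to 18494397) and 3439 bp from AT1G32650 (chromosome 1, 11807001 to 11807182). Within 50 kb of MYC2 lay 25 regions of the MYC2 summit lists, against 5.65 per 100 kb of the genome, and 12 MYC3 regions. The region nearest to AT1G32650 is among these 25. Within 50 kb of MYC3 lay 16 MYC3 regions, against 3.34 per 100 kb, and 3 regions of the MYC2 summit lists. Whether extra copies of the tagged gene give part of these regions was not tested for MYC2 and MYC3. For MYC3 the regions next in rank were 256 bp from AT2G22760 (chromosome 2, 9677512 to 9677664) and 85 bp from ACT1, an actin gene (chromosome 2, 15778773 to 15778939). STZ had a MYC3 region inside the gene (chromosome 1, 9649188 to 9649377, 3 replicates) and a MYC2 region there (9649174 to 9649364, 2 replicates). ANAC055 had MYC2 and MYC3 regions inside the gene (chromosome 3, 5234468 to 5234639 for MYC2 and 5234377 to 5234594 for MYC3) and others 347 bp away (MYC2 at 5234028 to 5234192). The 3 ANAC055 regions of highest rank lay next to ANAC055 itself, 86 to 1212 bp away, and 100 of the 388 ANAC055 regions lay within 50 kb of that gene. Whether a region within a gene is in an exon, an intron or a UTR was not analysed here.

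STZ was the only factor with air and JA lists. Air gave 241, 8 and 19 summits and JA 21 and 5. Of 17 JA regions, 12 had an air region at the same place (234 air regions). An exact permutation test of the number of windows (two-sided p = 0.6) could not have passed, since its smallest possible p with 3 against 2 lists is 0.2. Of the JA regions, 12 lay within 50 kb of the STZ gene, and so did 17, 7 and 5 summits of the 3 air lists. All 4 JA regions found in 2 replicates lay there, as did 5 of the 12 air regions found in at least 2. Whether extra copies of the tagged gene give part of these regions was not tested for STZ.

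Bound genes were set against the 2 h time point, the time of the ChIP-seq samples (21356 genes tested and assignable). Of the 727 genes higher at 2 h, 170 (23.4%) were bound by MYC2, against 16.3% of the other genes (odds ratio 1.57, 95% confidence interval 1.31 to 1.87, Fisher's exact p = 1.3e-06), and 148 (20.4%) were bound by MYC3, against 12.0% (odds ratio 1.87, 1.54 to 2.26, p = 3.85e-10). With the summit lists alone MYC2 had 213 (odds ratio 1.77, Fisher's exact p = 4.47e-11). Of the 161 genes lower at 2 h, 35 were bound by MYC2 (odds ratio 1.41, Fisher's exact p = 0.0876) and 27 by MYC3 (1.44, p = 0.0909), neither past 0.05. Both passed at other settings: within 3000 bp (MYC2 1.48, Fisher's exact p = 0.0334; MYC3 1.51, p = 0.0414) and with regions of 1 replicate or more (MYC2 1.49, p = 0.0166; MYC3 1.70, p = 0.00216). MYC2 regions of 3 replicates or more turned the direction (0.781, Fisher's exact p = 0.709). The MYC2 summit lists gave 39 (1.34, Fisher's exact p = 0.132). ANAC055 bound 232 of the genes tested, 8 of the higher genes (odds ratio 1.01, 0.431 to 2.04) and 0 of the lower. In ANAC055 replicates 1, 2 and 3, 38.0, 4.63 and 69.5% of nuclear summits lay within 50 kb of the ANAC055 gene, which leaves few elsewhere in replicates 1 and 3. The p-values treat genes as independent.

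DAP-seq lists held 8052 binding events for ERF1, 5399 for WRKY51, 4347 for ORA59, 3679 for ATAF2, 2787 for ZAT18, 1766 for RVE2, 1469 for TCP23, 879 for HY5 and 115 for DREB2B, 1 list per factor without replicates. No factor's bound genes were enriched or depleted among the genes higher or lower at 2 h after adjustment over 18 tests. The nearest were ERF1 and ATAF2, each with an adjusted p = 0.0507, at 219 of 727 higher genes bound by ERF1 (30.1% against 25.5%; odds ratio 1.26, Fisher's exact p = 0.00563) and 110 by ATAF2 (15.1% against 11.5%; odds ratio 1.37, p = 0.00383). Bound by WRKY51 were 99 (odds ratio 0.768, Fisher's exact p = 0.0156), and TCP23 bound 14 of 161 lower genes (odds ratio 2.06, p = 0.0183). At other settings some passed after adjustment: ERF1, ORA59, ATAF2 and WRKY51 (fewer bound) among higher genes within 500 bp, ERF1 and WRKY51 with higher scores, and TCP23 among lower genes within 3000 bp. Transcripts of the DAP-seq factors also moved in the time course: HY5 and RVE2 passed as given, TCP23 at 1 h (0.83 ± 0.20) and 24 h (0.82 ± 0.20), and ERF1, ORA59, ZAT18 and DREB2B at no time by edgeR. With the replicate block ERF1 passed at 0.5, 12 and 24 h, ORA59 at 12 and 24 h, ZAT18 at 1 h, TCP23 at 2 h, ATAF2 at 0.5 and 12 h and HY5 at 24 h as well.

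Genes that were called higher at 4 h in the time course were split by MYC2 binding and followed in the interaction of the second experiment, whose libraries had no part in choosing them. The 13 bound genes had a mean difference of 1.51 (log2, myc2 minus Col-0), and all 13 had a larger response in myc2, which passed limma's fry. The 20 genes not bound had a mean of 0.05, with 11 larger, and did not pass. Fry gave these the direction down although mean and median (0.11) are above 0. Bound genes differed from the others by limma's camera as well, at the preset correlation, the only one used to compare bound with other genes. The MYC2 summit lists gave a mean of 1.23 for 16 bound genes and 0.05 for 17 others. With genes called at 4 h under the replicate block the mean was 0.36 for 107 bound genes, 69 of them with a larger response in myc2, against 0.07 for 313 others. Genes chosen from Col-0 of the first experiment gave a mean of 0.24 for 122 bound genes, which did not pass fry, and 0.25 for 199 others, which did, and camera found no difference between these groups. The interaction of the first experiment gave −0.26 for the 13 bound genes, with 10 smaller in myc2, which did not pass fry. There camera placed the bound genes below the 20 others (mean 0.21), the opposite of the second experiment. The first experiment has 2 libraries per group, and its myc2 4 h replicate 1 held 3.15 M counts.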

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

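The test of MYC3 regions near ANAC055 and all 3 tests of the light response list were chosen after the result was seen; the other tests were written down before.

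Differences between groups brought these results here. The JA response differed between myc2 and Col-0 for 1 gene at 4 h in the first experiment, and for 12, 57 and 66 genes at 0.5, 1 and 4 h in the second. Genes named at 4 h were SOT17 (2.21), STZ (2.04), ECS1 (3.10), MYC2 (0.77), ILL6 (1.06), SUR1 (1.69), CYP94C1 (2.01), CB5-C (2.02), CYP94B3 (1.08), CYP83B1 (1.72), CYP79B2 (2.16) and BCB (2.21), with GGPS6 (−1.86), AT2G34020 (−0.87), AT3G57710 (−0.65) and AT4G36440 (−0.62) smaller in myc2. In the time course every DREB2B library lay above the 0 h libraries at 0.25, 0.5, 1, 8 and 12 h (log2 0.90, 0.76, 0.61, 0.26 and 0.42) and below them at 4 h (−0.39). RVE2 lay above at 0.5 and 1 h (0.74, 0.85) and below at 2, 4 and 8 h (−1.13, −1.28, −0.84). Of all genes tested, 12.47, 8.325, 12.5, 25.99, 17.95, 17.98 and 23.3% lay apart from 0 h in either direction at 0.25, 0.5, 1, 2, 4, 8 and 12 h. Chance gives 10%, and all times share the same 0 h libraries. Against 0 h edgeR called RVE2 lower at 2 and 4 h and DREB2B at no time; for both genes the difference between the early and the later times was not tested.

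A replicate far from the others, and summits outside the nuclear genome, brought these here. MYC2 replicate 2 had 132 chloroplast summits and 1.585% of its summits within 50 kb of the MYC2 gene, both far from the other 3 replicates; 8 such comparisons were made, and chance gives about 1 in 20. MYC3 replicate 3 had 11 chloroplast summits, ANAC055 replicate 2 had 283, and ANAC055 replicate 3 had 266 mitochondrial summits.

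The JA response in myc2 was mostly smaller than in Col-0 at 1 h and mostly larger at 4 h. If the shared 0 h libraries stood apart, genes would differ alike at both times. The 62 genes larger at 4 h had a median difference of 0.10 at 1 h against 1.22 at 4 h, which speaks against it for these genes as a set. They were chosen on the 4 h difference, which raises its median. A smaller response at 1 h could mask such an offset, though none of the 62 was among the 55 genes called smaller at 1 h. The genotype difference of the 62 genes at 0 h was not examined as a set. For single genes such as ECS1 the difference does lie in the 0 h libraries. With all libraries thinned to the smallest total, 40 genes were larger and 3 smaller at 4 h, and 1 larger and 31 smaller at 1 h, which speaks against library size. Of 100 splits of the libraries, 12, 14 and 9 gave at least as many genes at 0.5, 1 and 4 h (up to 2292, 1955 and 1429). Apart from the real one these exchange genotypes at 1 time and so bring in genotype effects, which leaves them unable to measure chance. The 28 splits without such an exchange gave 0. They put both genotypes in each of the groups compared, so genotype differences widen the spread within groups. For that reason they cannot measure chance either. The design's biological explanation, a changed JA response without full MYC2 function, remains open, and the first experiment called 1 gene at 4 h (14 by DESeq2, 48 without a filter on counts and 8 with the replicate block).

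Light response genes were higher after JA in the time course and the second experiment. JA alone in every experiment does not account for it, since their mean at 4 h in Col-0 of the first experiment was −0.26 (95% confidence interval −1.05 to 0.53) against 1.09 in the second. The names of the untreated files of the first experiment mention air, so its untreated libraries may differ from those of the second in elapsed time. Near-identical copies do not account for the whole of it either, since 8 of 12 members outside the LHCB1, RBCS and ELIP copies were higher at 2 h: LHCB2.1, which has a close copy too, and LHCB3, LHCA1, LHCA4, PSAD1, HY5, CHLH and HEMA1. Light or handling between 0 h and harvest could raise them. The mean of 1.24 at 0.5 h in myc2 cannot tell this from JA, because by the labels the design has no untreated library of a later time. The untreated libraries of the first experiment may have been kept in air for 4 h. Its −0.26 would then compare matched times, which the labels do not settle.

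Of the ANAC055 regions, 100 lay within 50 kb of the ANAC055 gene, in a stretch of 55.7 kb. Extra copies of the tagged gene with its flanks in the line could give this, and 53.0% of these regions were inside genes, near the 59.4% of the stretch that genes cover, where 35.1% of the other regions were. Binding at the gene itself does not account for it, since 82 of the regions lay more than 3 kb away. A stretch that gives regions with any tagged factor does not account for the whole of it, since 0.176% of MYC3 regions lay within 50 kb of the gene against 25.8% of ANAC055 regions, but part stays open: these were 7 MYC3 regions against 3.34 per 100 kb of the genome, and 15 MYC2 regions against 5.65.

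For each time of the time course and each 2-group comparison of the second experiment, 1 of 10 splits of the libraries, the real one, gave as many genes, and 10 splits are too few to tell it from chance. In the time course the other splits gave 0 genes, those that part as many pairs of the same number included; in the second experiment they gave 0 except 30 for Col-0 at 0.5 h and 1 each for Col-0 at 1 h and myc2 at 4 h.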

How the results depend on the processing

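The settings that leave out replicate 1 of every time, or the shallowest library, or MYC2 replicate 1, and the choice of genes from the blocked fit, were chosen after the results were seen. Of 128 gene counts under settings planned beforehand, 76 stayed within 1.5 times the reported count and 52 did not; of 16 under later settings, 10 did. Without 1 library 76 of 146 gene counts did and 70 did not. Of 101 planned binding and list results 66 stayed, 11 moved, 12 changed direction and 12 changed side of the threshold; of 9 later ones 5 stayed, 1 moved, 2 changed direction and 1 changed side. For named genes, 919 of 965 values kept direction and side of the threshold under other settings, and 1800 of 2072 without 1 library. Where a value below differs from the reported one, the cause was not tested. Leaving out a library can leave a group of the first experiment with 1 library, which is then assumed to vary like the other groups. The motif search and its window settings were not run, because no genome was at hand.

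With DESeq2 the time course gave 108, 187, 578, 1507, 275, 234 and 900 genes from 0.25 to 12 h. The first experiment gave 496 in myc2, 714 at 0 h and 14 for the interaction, and the second gave 52, 105 and 134 for the interactions at 0.5, 1 and 4 h. DESeq2 kept 906 of the 907 genes at 2 h. Only a fold of 2 or more left 505 genes at 2 h and 1495 at 24 h. In the second experiment it left 514, 1254 and 743 in Col-0, 761, 1191 and 1017 in myc2, and 100 at 0 h. Without a filter on counts the first experiment gave 907 in Col-0, 683 in myc2, 1120 at 0 h and 48 for the interaction. The second gave 797 at 0 h and 277, 190 and 281 for the interactions. Fitting only the groups compared gave 0, 10, 140, 20, 1 and 1297 genes at 0.25, 0.5, 1, 4, 8 and 24 h. It gave 905 in Col-0, 142 in myc2 and 625 at 0 h of the first experiment, and 124 at 0 h and 7 for the 0.5 h interaction of the second. Leaving out replicate 1 of every time gave 267, 478, 826, 19, 22 and 713 at 0.25, 0.5, 1, 4, 8 and 12 h.

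The labels give replicate numbers without saying that libraries of 1 number belong together. In the time course 96 of 108 pairs of libraries with the same number correlated above 0.1 after the group means were removed (mean 0.37, against −0.18 for other pairs), and 25 of 27 libraries correlated best with their own number, which is a hint from the data and not the design. In the first and second experiments the mean was 0.03 and −0.01. With the number as a block the time course gave 143, 201, 797, 2754, 590, 445, 1660 and 6891 genes from 0.25 to 24 h, and the first experiment 431 in myc2, 756 at 0 h and 8 for the interaction. All pairs pass at 6 of the 8 times, whose blocked counts and changed calls are in the report; the block changed no other call of a named gene or a list there.

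Without single libraries the counts ranged from 3 to 130 at 0.25 h, 39 to 256 at 0.5 h, 159 to 506 at 1 h, 331 to 806 at 2 h, 7 to 30 at 4 h, 1 to 91 at 8 h, 110 to 306 at 12 h and 2076 to 4307 at 24 h. In the first experiment they ranged from 148 to 292 in Col-0, 114 to 384 in myc2, 72 to 324 at 0 h and 0 to 13 for the interaction. In the second they ranged from 113 to 382 at 0 h, 2 to 53 for the 0.5 h interaction and 36 to 99 for the 4 h interaction. MYC2 regions ranged from 1290 to 6731 and ANAC055 regions from 140 to 339. Named genes whose sign changed were not called, with these log2 ranges: RVE2 −0.093 to 0.133 at 0.25 h; MYC3 −0.065 to 0.155 at 0.5 h, −0.089 to 0.116 at 2 h and −0.115 to 0.090 at 4 h; ORA59 −0.676 to 0.296 at 1 h. WRKY51 went from −0.139 to 0.273 at 1 h, −0.435 to 0.110 at 2 h, −0.085 to 0.428 at 4 h and −0.034 to 0.615 at 8 h. ANAC055 went from −0.484 to 0.377 and ERF1 from −0.030 to 0.949 at 2 h. ZAT18 went from −0.280 to 0.901 at 2 h, −1.025 to 0.896 at 4 h, −0.140 to 0.847 at 12 h and −0.454 to 0.912 at 24 h. At 4 h in Col-0 of the first experiment STZ went from −0.111 to 0.661 and ANAC055 from −0.534 to 0.757. In Col-0 of the second STZ went from −0.359 to 0.009 at 0.5 h and −0.087 to 0.245 at 4 h, and MYC3 from −0.005 to 0.083 at 4 h. MYC3 went from −0.073 to 0.047 for the 0.5 h interaction and −0.174 to 0.008 in myc2 at 1 h. At 2 h MYC3 was 0.003 with DESeq2 and with RLE scaling and 0.008 with the block, and ANAC055 was −0.056 with the block.

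Of 277 list calls 108 held with an estimated correlation. Regions with a score at or above the median numbered 2963 for MYC2, 2065 for MYC3 and 179 for ANAC055. The share of MYC3 regions on MYC2 regions was 93.6% and 95.4% with windows of 50 and 250 bp either side, 91.5% for those scores, 90.3% with 1 replicate, 63.9% with 3 replicates and 91.6% with the MYC2 summit lists. In a logistic regression with expression and gene length the odds ratio for higher genes was 1.35 for MYC2, 1.513 for its summit lists and 1.618 for MYC3, each below the reported one and past 0.05. The odds ratio of MYC2 binding for lower genes was 1.481 within 3000 bp, 1.492 with 1 replicate and 0.781 with 3, and for MYC3 it was 1.506 and 1.703 at the first 2 of these; all but the 0.781 passed 0.05 by Fisher's exact test, which the reported ones did not. For DAP-seq, within 500 bp, higher genes had 1.273 for ERF1, 0.747 for WRKY51, 0.960 for RVE2, 1.309 for ORA59 and 1.345 for ATAF2. Within 3000 bp RVE2 had 0.973 and TCP23 0.999 for higher genes, and TCP23 2.439 for lower genes. With higher scores only, higher genes had 1.374 for ERF1, 0.545 for WRKY51, 0.756 for RVE2 and 1.015 for ZAT18, and lower genes 0.863 for RVE2, 1.019 for ZAT18 and 0.919 for ATAF2. MYC2-bound induced genes had a mean of 0.361 with the 107 genes from the blocked fit, 1.233 with the summit lists, 0.240 with genes of the first experiment, 0.223 with these and the summit lists, and −0.264 in the interaction of the first experiment. Genes not bound had 0.251, 0.279 and 0.211 there, and 0.073 with genes from the blocked fit. Without a filter the correlation across genes was 0.0759 between the time course and the first experiment, 0.174 between the time course and the second experiment and 0.187 between the first and the second.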

Other observations

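In the second experiment STZ transcript rose in myc2 at each time, by 1.73 ± 0.30 at 0.5 h, 1.54 ± 0.32 at 1 h and 2.11 ± 0.30 at 4 h (log2, SE, n = 3), and in Col-0 at 1 h only among the times called by edgeR. In Col-0 it was at 3.24 ± 0.518 CPM at 0 h, 6.36 ± 0.422 at 1 h and 3.44 ± 0.8003 at 4 h, and in myc2 at 1.67 ± 0.708, 4.81 ± 1.77 and 7.23 ± 0.718 (SD, n = 3), so myc2 started from a lower mean.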
